A study of Homo sapiens with 12 samples.

How the data were processed

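The series measured messenger RNA in A549 and H1299, established human non-small-cell lung cancer cell lines, after lentiviral overexpression of VGF or delivery of an empty vector. VGF encodes a secreted neuroendocrine precursor protein. The design is factorial, with 2 cell lines and 2 vectors, which gives 4 groups of 3 libraries each. The submitters' design text calls the replicates biologically independent. Groups were taken from the titles and the sample characteristics. The free-text treatment note of all 12 libraries speaks of the empty vector, and it was not used for grouping. Per the labels' protocols, messenger RNA was captured from total RNA on beads, and the lines were grown in different media. The comparison of the lines therefore includes the medium.

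The authors deposited raw counts per feature, whole numbers whose totals differ between libraries. The authors also deposited FPKM values for the same features, which are scaled by feature length and library size. The submitters' processing notes name the genome build GRCh38 and DESeq2, with no version. The aligner, the counting tool, the annotation release, any filter and whether strand was used are not given in the sources used here. Each table holds 26535 features, of which 19974 carry an Ensembl gene ID and 6561 carry a newly assigned gene name, called unannotated loci here. A further 18 lines of each table hold stray annotation text in place of a feature and were left out. Symbols that a spreadsheet had turned into dates were restored by ID for 27 features. All 19974 Ensembl IDs were found in GENCODE release 29, and its 1-based GRCh38 coordinates are given.

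Library totals ran from 31378171 to 41919484 counts. The median SD of log2 CPM between replicates of a group was 0.0768 to 0.0890 over 11199 well expressed features. No pair of replicates agreed within sampling noise, since the chi-square statistic per degree of freedom was 7.82 to 21.8 for the 12 pairs within groups. Intervals are exact binomial intervals over genes, and floors cover counting error only. A group whose libraries all hold 0 counts was set to a floor of 3 counts over the group, which is 0.0297 CPM for A549 with empty vector, 0.0291 for A549 with VGF, 0.0231 for H1299 with empty vector and 0.0244 for H1299 with VGF. A fold given as "at least" sets the other group against this floor. It leaves out the counting error of that other group and is no strict bound.

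Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group and Benjamini-Hochberg adjustment. One fit of the 12 libraries held the 4 group means, without a block. It had 8 residual degrees of freedom and 4.44 prior degrees of freedom. The filter left 18228 features, 14865 with an Ensembl ID and 3363 unannotated loci. The contrasts were VGF against empty vector in each line, the difference between those effects (H1299 minus A549), and H1299 against A549 with empty vector. A feature was called at an adjusted p under 0.05, and every adjusted p of a gene comes from this test unless another tool is named. Standard errors were derived from the F statistic. CPM values of single genes are counts scaled to the library total multiplied by its TMM factor (CPM), as mean ± SD of 3 libraries. These factors were 0.919 to 0.940 in A549 libraries and 1.06 to 1.09 in H1299 libraries. CPM sums over several genes were scaled to the library total alone, without the TMM factor.

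38 gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives except those named below as added. They cover secretory, adhesion, matrix, growth, death, immune, signalling, stress and metabolic genes, lung lineage genes, ribosomal, mitochondrial and histone genes, markers of other cell types, and genes known to be deleted in these lines. 35 lists had at least 5 tested members and were tested with camera in limma 3.58.1, at a preset correlation between genes of 0.01, with adjustment over the lists of a contrast. The same test was run with a correlation estimated from the data. None of the list calls held there: the smallest adjusted p was 0.282 in A549, 0.148 in H1299 and 0.350 for the difference between lines. A second list of 20 endothelial genes was written after the markers of the first had been seen and before its own counts were read.

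VGF was always named. In each line the 8 largest rises and the 8 largest falls were named among called genes with a symbol, at least 5 CPM in a group and the same direction in each of the 9 treated-control pairs. For both lines, up to 6 genes per direction meeting these criteria in both were to be named, and none did. For the difference between lines, up to 6 genes per sign were named among those called in at least 1 line with at least 5 CPM in a group. Up to 3 called members per direction were named for each list, and the 2 members with the smallest p for called lists without a called member. Marker and identity genes are given as levels. Some genes that the rule names, and 1 list, are not reported here.

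The procedure was tested on simulated counts. For A549, 76.2% of the genes changed 1.5-fold were recovered, 92.7% of those changed 2-fold and 100% of those changed 4-fold, with 6.35% false calls among 189. For H1299 the shares were 82.4%, 94.2% and 97.3%, with 3.19% false calls among 188. The shares recovered cover simulated genes at 5 CPM or more. The false calls cover all genes tested, 17796 for A549 and 17816 for H1299. Counts were drawn independently for each gene, with the spread estimated from these data. Genes that move together and a library with foreign transcripts were not simulated, so the shares hold for that setting alone.

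The alternatives tried were median-ratio and upper-quartile scaling, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, each line fitted alone, a replicate block, a log2 fold change of at least 1, deposited FPKM with limma at a pseudocount of 1 or 0.1 (mean FPKM of at least 0.5) or without that filter, VGF removed, each library left out in turn, and other list tests. Added after the data were seen were a fit without A549 VGF library 2, robust empirical Bayes, and features with an Ensembl ID alone. Overlap of calls between lines was tested with Fisher's exact test, with VGF left out. Figures were drawn with matplotlib 3.10.9.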

Results

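RNA-seq libraries were compared from A549 cells, a lung adenocarcinoma line, and H1299 cells, a non-small-cell lung carcinoma line, each carrying a VGF lentivirus or an empty vector. Each of the 4 groups held 3 libraries. CDKN2A, known to be deleted in A549, had 11, 0 and 0 counts in the A549 control libraries and 0, 51 and 0 in the A549 VGF libraries, against 5158 to 7075 in H1299 libraries. CDKN2B had 0 to 4 counts in the A549 control libraries and 0, 30 and 0 in the VGF libraries, against 5243 to 6110 in H1299. MTAP, a neighbour of both, was lower in A549 but not near 0, with 274 to 522 counts in A549 and 3457 to 4080 in H1299.

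The first question was whether the vector raised VGF. VGF (ENSG00000128564, GRCh38 chromosome 7, 101162509 to 101165593, minus strand) rose in A549 from 2.43 ± 0.373 to 1283 ± 80.1 CPM (SD, n = 3), a 527-fold change. In H1299 it rose from 85.6 ± 7.26 to 980 ± 119 CPM, an 11.5-fold change. The log2 fold changes were 9.04 (SE 0.137, adjusted p = 6.1e-13) and 3.52 (SE 0.0980, adjusted p = 1.12e-09). H1299 cells with empty vector held 35.1-fold more VGF than A549 cells (adjusted p = 1.21e-12), and the step in H1299 was smaller (difference in log2 fold change -5.52, adjusted p = 1.49e-09). In the deposited FPKM the means were 0.827 and 436 in A549 and 33.7 and 384 in H1299. Every VGF library was above every control library of its line. VGF took 0.112 to 0.127% of the counts of the A549 VGF libraries.

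**Figure D1:**
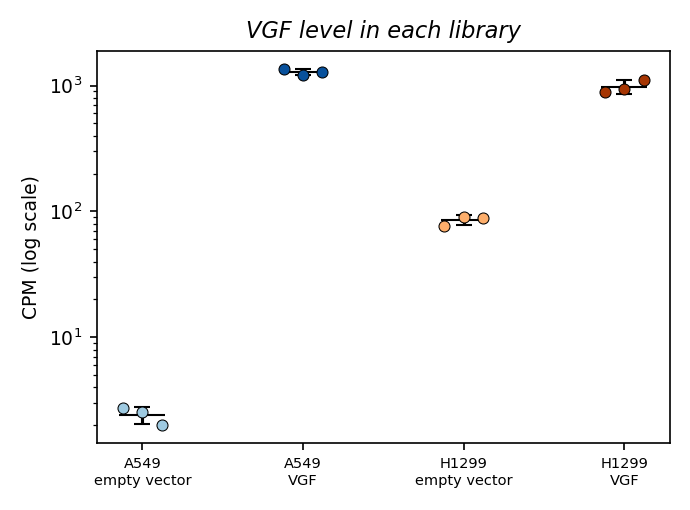
VGF in CPM (logarithmic axis) in each of the 12 libraries, as points, by line and vector, with the mean and SD of each group of 3. The empty-vector means are 2.43 CPM in A549 and 85.6 CPM in H1299, and the VGF means are 1283 and 980 CPM.

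VGF overexpression in A549 raised 74 genes, VGF included, and lowered 70 among 18228 tested, while DESeq2 called 437 higher and 299 lower and limma voom 155 and 179. CPS1 (ENSG00000021826, chromosome 2, 210477682 to 210679107, plus strand), the mitochondrial enzyme that opens the urea cycle, rose from 59.6 ± 8.07 to 152 ± 15.1 CPM (SD, n = 3), a log2 fold change of 1.35 (SE 0.144, adjusted p = 0.000953). LBH (ENSG00000213626, chromosome 2, 30231369 to 30323730, plus strand), a transcriptional cofactor, rose from 65.8 ± 4.27 to 140 ± 13.5 CPM (1.09, SE 0.0950, adjusted p = 0.000694). The cancer-testis antigens MAGEA3 (ENSG00000221867, chromosome X, 152698752 to 152702347, plus strand) and MAGEA6 rose by 1.21 and 0.77 on the log2 scale (SE 0.0748 and 0.0689, adjusted p = 9.41e-06 and 0.000369). MAGEA3 went from 12.9 ± 1.22 to 29.9 ± 2.44 CPM and MAGEA6 from 33.4 ± 3.63 to 56.9 ± 3.13 CPM. These paralogs are nearly identical, so how their reads were divided is uncertain.

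The other large rises in A549 were of PDK4, an inhibitor of pyruvate dehydrogenase (51.1 ± 14.96 to 97.2 ± 8.05 CPM, adjusted p = 0.0277), JUN, an AP-1 subunit (48.4 ± 4.84 to 86.5 ± 23.1 CPM, adjusted p = 0.0277), FSTL1, a secreted glycoprotein (39.5 ± 2.99 to 67.0 ± 17.3 CPM, adjusted p = 0.0245), and FBXO43, an inhibitor of the anaphase-promoting complex (4.73 ± 0.725 to 8.02 ± 0.550 CPM, adjusted p = 0.0322). Each of these calls was lost when 1 of several libraries was left out. A fit with 1 library fewer also has less power, so a loss does not show that the call rested on that library. PDK4 reached an adjusted p of 0.0965 without A549 control library 1, 0.109 without control library 2, 0.0606 without VGF library 1 and 0.0637 without VGF library 3. JUN reached 0.0615, 0.0964 and 0.0855 without A549 control library 1, 2 or 3, and FSTL1 0.103, 0.0729 and 0.0573. FSTL1 had 3402 counts in A549 VGF library 2, which held endothelial transcripts, against 1648 and 2004 in the other A549 VGF libraries. Without library 2 its log2 fold change was 0.529, against 0.764 with it, and the call was kept (adjusted p = 0.00413). FBXO43 reached 0.121 and 0.111 without A549 control library 1 or 2, and 0.0637, 0.0654 and 0.0565 without VGF library 1, 2 or 3.

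The largest falls in A549 were of SHISA3 and KHDRBS3. SHISA3 (ENSG00000178343, chromosome 4, 42397839 to 42402487, plus strand), an attenuator of WNT and FGF signalling, fell from 15.7 ± 1.02 to 1.05 ± 0.201 CPM (SD, n = 3), a log2 fold change of -3.89 (SE 0.306, adjusted p = 0.000106). KHDRBS3 (ENSG00000131773, chromosome 8, 135457457 to 135656722, plus strand), an RNA-binding splicing regulator, fell from 15.7 ± 2.70 to 2.43 ± 0.844 CPM (-2.68, SE 0.266, adjusted p = 0.000631). The transcription factor SOX2 fell from 5.89 ± 0.458 to 1.67 ± 0.474 CPM (adjusted p = 0.0379), the link protein HAPLN3 from 7.78 ± 0.918 to 2.72 ± 0.287 CPM (adjusted p = 0.0103), and the ubiquitin ligase RNF128 from 7.39 ± 1.59 to 3.47 ± 0.219 CPM (adjusted p = 0.00896). FCGBP, a mucin-like secreted protein, fell from 123 ± 11.2 to 68.2 ± 10.98 CPM (adjusted p = 0.0103). The glucose transporter SLC2A3 fell from 14.9 ± 3.32 to 8.61 ± 0.591 CPM (adjusted p = 0.0133). FBN2 (ENSG00000138829, chromosome 5, 128257909 to 128659185, minus strand), a microfibril protein, fell from 289 ± 7.37 to 169 ± 16.8 CPM (-0.78, SE 0.0722, adjusted p = 0.000414). SOX2 lost its call without A549 control library 1, 2 or 3 (adjusted p = 0.113, 0.111 and 0.0720), A549 VGF library 1 or 3 (0.0777 and 0.0890) or H1299 VGF library 1 (0.0618). HAPLN3 and SLC2A3 lost theirs without A549 VGF library 3 (0.0502 and 0.0552).

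**Figure D2:**
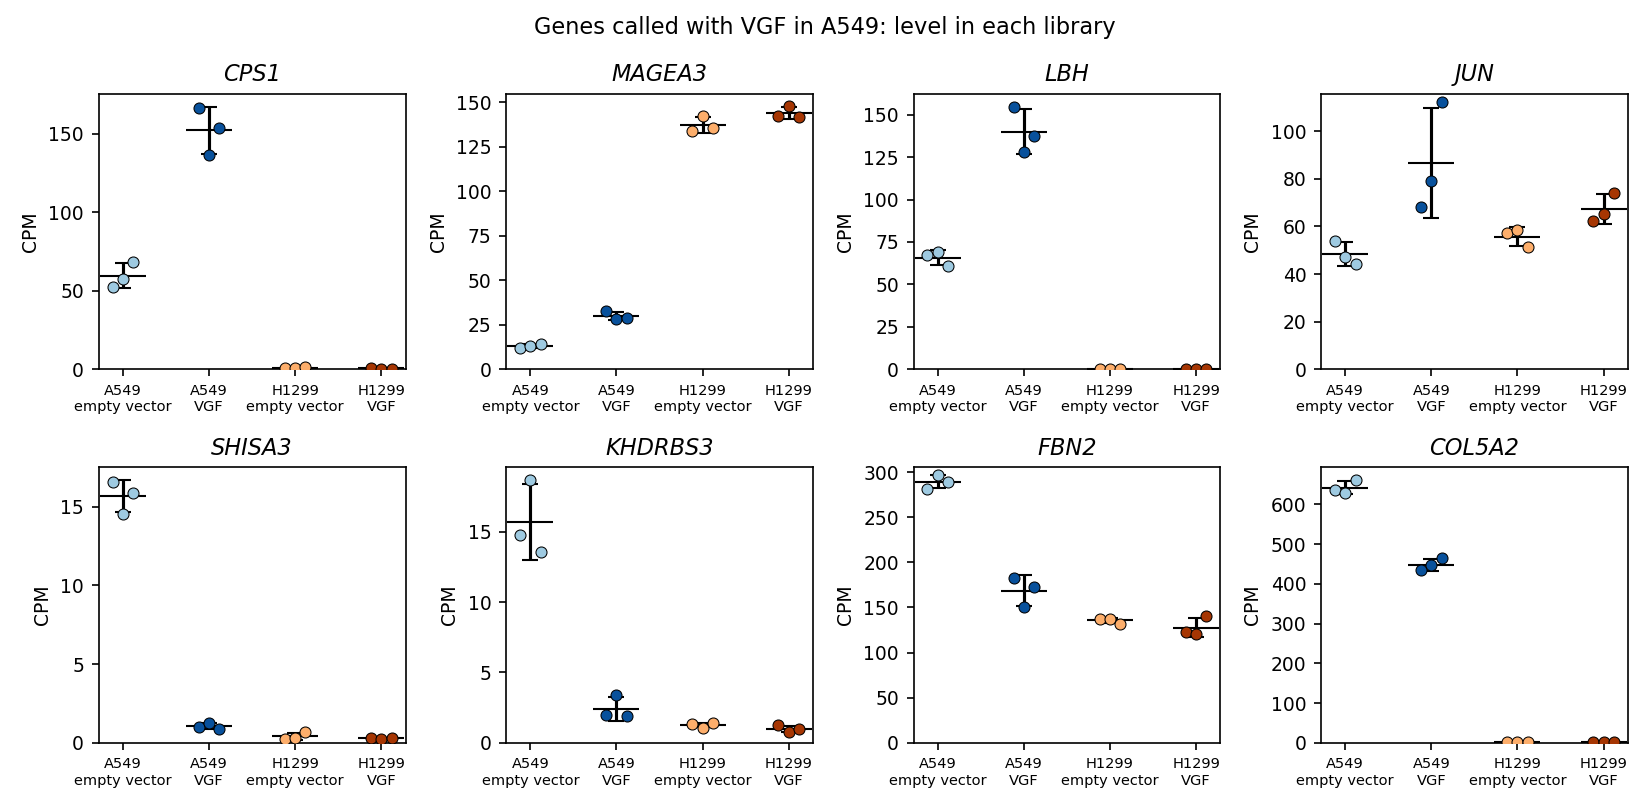
CPM of 8 genes in each of the 12 libraries, as points, by line and vector, with the mean and SD of each group of 3. In A549, CPS1, MAGEA3, LBH and JUN are higher with VGF and SHISA3, KHDRBS3, FBN2 and COL5A2 lower. The JUN values of the A549 VGF group lie farther apart than those of the A549 control group (SD 23.1 against 4.84 CPM).

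Of the 144 genes called in A549, 133 had an Ensembl ID and 11 were unannotated loci. Most changes were small: the median absolute log2 fold change was 0.43, and 15 rises and 21 falls exceeded 1. 28 of the 144 genes stayed under 5 CPM, 10 had no count in the 3 VGF libraries and 6 had none in the 3 control libraries. At an unadjusted p under 0.05 there were 2528 features, or 13.9%. The balance of directions depended on the processing: the deposited FPKM with a pseudocount of 1 gave 55 genes higher and 78 lower, upper-quartile scaling 60 and 83, and A549 fitted alone 76 and 103. The number of calls was 52 without A549 control library 1, 76 without control library 2, 83 without control library 3, 57 without VGF library 3 and 94 without H1299 control library 1. Without A549 VGF library 2, which held transcripts of endothelial genes described with the other cell types, 96 genes were called, 51 higher and 45 lower, and 67 of them were among the 144. The count was lower than 144 whichever library was left out.

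**Figure D3:**
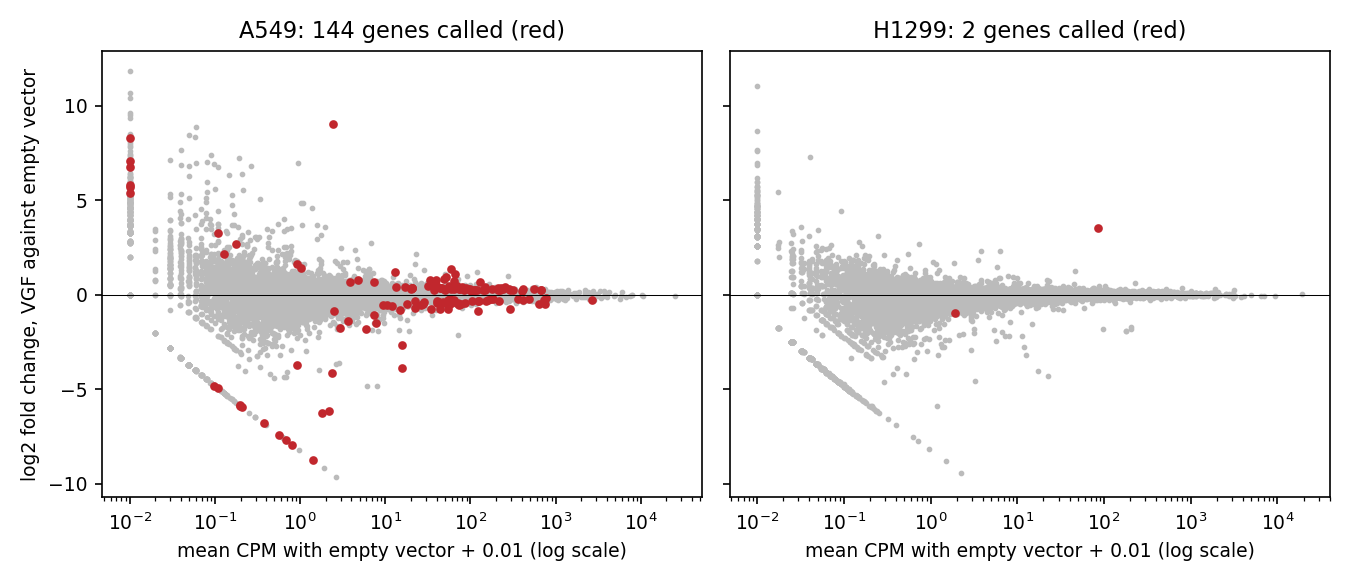
Log2 fold change with VGF against the mean CPM of the empty-vector libraries plus 0.01 (logarithmic axis) for the 18228 tested features, A549 in one panel and H1299 in the other. Called features are in red, 144 in A549 and 2 in H1299, and most of the A549 calls above 5 CPM lie within 1 log2 unit of 0.

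Cell cycle and mitosis genes rose together in A549. All 48 tested members had a positive log2 fold change, with a median of 0.18 (camera, adjusted p = 1.75e-19; adjusted p = 0.282 with an estimated correlation). PTTG1, the securin that restrains separase until anaphase, rose from 88.1 ± 4.41 to 113 ± 4.23 CPM (adjusted p = 0.00896), and the spindle factor TPX2 from 223 ± 7.36 to 267 ± 8.16 CPM (adjusted p = 0.0103). CCNA2, cyclin A2, rose from 75.5 ± 1.91 to 92.2 ± 5.94 CPM (adjusted p = 0.0490), a call that was kept without H1299 VGF library 3 and lost without any of the other 11 libraries, at up to 0.184. These 3 members passed over all genes, and 23 rose when adjusted over the list alone. Without A549 VGF library 2 the median was 0.183 (adjusted p = 1.96e-18).

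YAP/TEAD target genes also rose in A549, with 22 of 25 positive and a median of 0.14 (camera, adjusted p = 0.000212; adjusted p = 0.282 with an estimated correlation), and 6 rose when adjusted over the list alone. No member passed over all genes. CTGF stood at 22.8 ± 0.624 and 100 ± 92.4 CPM (adjusted p = 0.0582), with 8075 counts in A549 VGF library 2 against 1122 and 1950 in the other VGF libraries. WWC1 stood at 136 ± 9.59 and 169 ± 14.2 CPM (adjusted p = 0.0598). CTGF was called without VGF library 1 (0.0138) or 2 (0.00766), and WWC1 without VGF library 2 (0.0399). TGF-beta pathway genes rose by a median of 0.16, with 16 of 25 positive (adjusted p = 0.0174; adjusted p = 0.320 with an estimated correlation), and 7 rose when adjusted over the list alone. Among them TGFBI stood at 760 ± 44.4 and 929 ± 55.2 CPM (adjusted p = 0.0528, and 0.0314 without VGF library 2), and PMEPA1 at 54.7 ± 4.97 and 73.3 ± 3.72 CPM (adjusted p = 0.0598, and 0.0377 without H1299 control library 2). Without A549 VGF library 2, the library with endothelial transcripts, the medians were 0.0807 for the YAP list and 0.119 for the TGF-beta list.

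Mesenchymal genes rose by a median of 0.21, with 20 of 28 positive (adjusted p = 0.0348; adjusted p = 0.378 with an estimated correlation). 8 rose and 2 fell when adjusted over the list alone. The only member called over all genes, the hyaluronan receptor CD44, fell from 774 ± 12.2 to 693 ± 13.2 CPM (adjusted p = 0.0401), a call kept only without H1299 VGF library 3 and otherwise lost at up to 0.114. The list lost its call without A549 control library 3 (0.173), H1299 control library 2 (0.0810) or A549 VGF library 2 (0.0658, median 0.105). Ribosomal protein genes rose by a median of 0.063, with 44 of 53 positive (adjusted p = 0.00151, and 0.102 without A549 control library 3; adjusted p = 0.536 with an estimated correlation), and none passed when adjusted over the list alone. RPS15 and RPL12 had the smallest p of its members (adjusted p = 0.105 and 0.164).

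Receptor tyrosine kinase and EGF family genes fell in A549, with 4 of 21 positive and a median of -0.15 (camera, adjusted p = 0.00656; adjusted p = 0.320 with an estimated correlation). 2 rose and 5 fell when adjusted over the list alone. FGFR1 stood at 224 ± 12.3 and 187 ± 10.1 CPM (adjusted p = 0.0676), and TGFA at 21.4 ± 2.08 and 26.9 ± 1.15 CPM (adjusted p = 0.0702, and 0.0410 without A549 control library 1). NF-kB and cytokine genes fell, with a median of -0.094 and 11 of 32 positive (adjusted p = 0.0188, and 0.143 without A549 VGF library 1; adjusted p = 0.320 with an estimated correlation). 1 rose and 7 fell when adjusted over the list alone. The mitochondrial superoxide dismutase SOD2 (ENSG00000112096) fell from 360 ± 5.62 to 311 ± 8.38 CPM (adjusted p = 0.0376), the NF-kB inhibitor NFKBIA from 123 ± 4.85 to 99.2 ± 4.95 CPM (adjusted p = 0.0473) and the adaptor TRAF1 from 12.02 ± 0.220 to 7.95 ± 1.52 CPM (adjusted p = 0.0485). With 1 of the 12 libraries left out, SOD2 lost its call in 9 cases (up to 0.125), NFKBIA in 11 (up to 0.184) and TRAF1 in 11 (up to 0.140).

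Interferon-stimulated genes fell by a median of 0.112, with 15 of 41 positive (adjusted p = 0.0352; adjusted p = 0.378 with an estimated correlation), and 1 rose and 4 fell when adjusted over the list alone. IRF1 stood at 55.5 ± 0.437 and 43.9 ± 1.32 CPM (adjusted p = 0.0914, and 0.0355 without H1299 VGF library 3). The interferon list lost its call without A549 control library 3 (0.373), VGF library 2 (0.0566) or VGF library 3 (0.171). MHC class I presentation genes fell by a median of 0.0845, with 4 of 16 positive (adjusted p = 0.0258, 0.135 without A549 control library 2 and 0.0787 without VGF library 1; adjusted p = 0.320 with an estimated correlation). No member passed when adjusted over the list alone; HLA-B and NLRC5 had adjusted p values of 0.173 and 0.334, and HLA-B 0.0308 without A549 control library 3. Fatty acid genes fell by a median of 0.0971, with 7 of 23 positive (adjusted p = 0.0258, 0.0601 without A549 VGF library 1 and 0.0566 without VGF library 2; adjusted p = 0.320 with an estimated correlation). The desaturase SCD fell from 2651 ± 84.4 to 2221 ± 100.3 CPM (adjusted p = 0.0198, 0.0818 without A549 control library 1 and 0.0569 without VGF library 1), and 2 members fell when adjusted over the list alone. Mitochondrially encoded genes fell by a median of 0.0926, with 0 of 13 positive (adjusted p = 0.0220; adjusted p = 0.658 with an estimated correlation). That call was lost without A549 control library 1 (0.112) or 2 (0.118) or VGF library 1 (0.114) or 2 (0.0715), and MT-CYB and MT-ATP8 had adjusted p values of 0.319 and 0.345.

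Called genes also stood in lists that did not pass in A549. The matrix genes FBN2 and COL5A2, a collagen V chain (642 ± 16.6 to 448 ± 15.1 CPM, adjusted p = 0.00236), fell within a list of 37 with a median of 0.091 (adjusted p = 0.612); its test pointed downward, against the sign of the median. Of 20 neuroendocrine granule genes (median -0.037, adjusted p = 0.248), the calcium sensor SYT1 fell from 22.3 ± 2.53 to 13.5 ± 2.05 CPM (adjusted p = 0.0430) and the granin SCG2 from 2.47 ± 0.226 to 1.34 ± 0.252 CPM (adjusted p = 0.0441). SYT1 kept its call only without H1299 VGF library 1 (otherwise up to 0.111), and SCG2 lost it whichever library was left out (0.0600 to 0.121). Of 26 ERK output genes (median 0.095, adjusted p = 0.248), JUN and the AP-1 subunit JUNB rose (JUNB 64.8 ± 3.903 to 109 ± 23.8 CPM, adjusted p = 0.0405, lost with 8 of the 12 libraries, up to 0.138). The ERK phosphatase DUSP5 fell from 86.6 ± 5.20 to 64.9 ± 3.29 CPM (adjusted p = 0.0210), and lost its call without A549 control library 2 (0.0539) or 3 (0.0660) or VGF library 2 (0.0572) or 3 (0.0598). In the cholesterol list (median 0.018, adjusted p = 0.612) HMGCS1, an enzyme of the mevalonate pathway, rose from 231 ± 9.71 to 297 ± 9.14 CPM (adjusted p = 0.00912). Without A549 VGF library 2, which held endothelial transcripts, the median was 0.036 for the matrix list and 0.041 for the ERK list. For the granule list, with 22 members then tested, it was -0.070. JUNB and HMGCS1 share 14.2% and 14.95% of their exonic bases with genes on the opposite strand, CDCA7L 20.4%, IRF1 22% and ACAT2 52.3%. NDUFB8 shares 33.8% with a gene on the same strand and 16.3% with one on the opposite strand, so part of the counts of these genes is uncertain.

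The remaining lists did not pass in A549. The stemness list (median -0.11, adjusted p = 0.0515), which holds SOX2 and CD44, and the hypoxia list (0.053, 0.480), which holds SLC2A3, each had called members. Medians and adjusted p values were 0.11 and 0.338 for neurotrophin genes, 0.072 and 0.992 for epithelial genes, 0.024 and 0.318 for proteases, 0.0072 and 0.612 for apoptosis regulators, and 0 and 0.612 for WNT and Notch genes. They were -0.028 and 0.109 for the unfolded protein response, 0.027 and 0.527 for ATF4 targets, 0.017 and 0.344 for glycolysis, 0.0027 and 0.527 for NRF2 targets, and 0.036 and 0.206 for angiogenesis regulators. They were -0.15 and 0.248 for lung lineage genes, 0.022 and 0.527 for nuclear oxidative phosphorylation genes, 0.14 and 0.527 for replication histones, and -0.026 and 0.612 for heat shock genes. The mean of the neurotrophin and apoptosis lists and the test of the NRF2 list had the sign opposite to the median. Without A549 VGF library 2, the library with endothelial transcripts, the median turned to -0.076 for proteases, -0.042 for angiogenesis regulators and -0.0065 for cholesterol genes (adjusted p = 0.891, 0.986 and 0.410). For epithelial genes it was 0.14 without that library (adjusted p = 0.323). Of the proposed receptors of VGF peptides 2 genes were tested, with a median of -0.022 in A549. In H1299 their median was 0.221, and 2 rose when adjusted over the list alone. The median difference between the lines was 0.243, and 2 had a higher effect in H1299 when adjusted over the list alone. In each of these contrasts 0 passed over all genes.

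**Figure D4:**
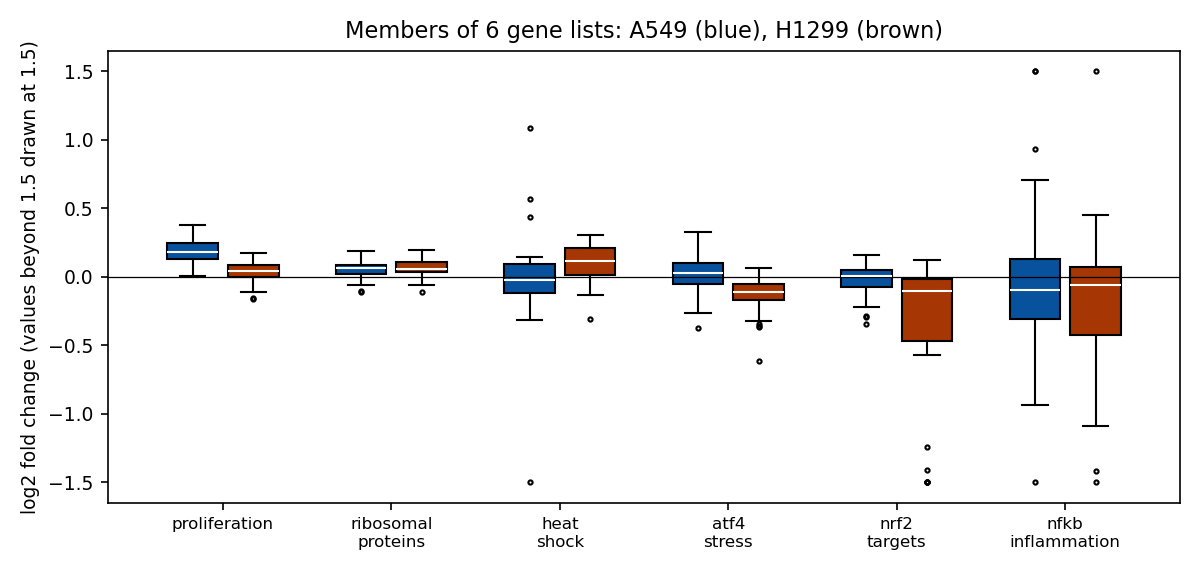
Log2 fold changes of the members of 6 gene lists with VGF in A549 (blue) and H1299 (brown), as boxes from the lower to the upper quartile with the median as a white line. Values beyond 1.5 are drawn at 1.5. The lists are cell cycle, ribosomal protein, heat shock, ATF4, NRF2 and NF-kB genes. The cell cycle list has a median of 0.18 in A549 and 0.041 in H1299, and the heat shock list -0.026 in A549 and 0.11 in H1299.

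Markers of other cell types showed 1 A549 library apart from the rest. A549 VGF library 2 held 3305 counts of PECAM1, 3387 of CDH5, 1559 of VWF and 1077 of KDR, against at most 61, 21, 17 and 7 in any other A549 library. The 11 endothelial markers summed to 334 CPM there, to at most 40.2 CPM in the other A549 libraries and to at most 4.27 CPM in H1299. The list of 8 tested endothelial markers rose in A549 by a median of 6.78 (camera, adjusted p = 0.000596; adjusted p = 0.378 with an estimated correlation), all 8 when adjusted over the list alone. None passed over all genes; VWF and KDR had adjusted p values of 0.106 and 0.116. Without that library the median was 0.80 (adjusted p = 0.0145), on markers that, apart from ESAM, had at most 61 counts in the other A549 libraries. Fibroblast markers had a median of 0.086 (adjusted p = 0.785), and 0 without that library (adjusted p = 0.819). Leukocyte markers had a median of -0.21 (adjusted p = 0.0515), and -0.046 without that library (adjusted p = 0.190), with 1 called member: the lysosomal protein CD68 fell from 70.6 ± 5.29 to 52.7 ± 2.96 CPM (adjusted p = 0.0187). It lost its call without A549 control library 2 (0.0576) or 3 (0.0594) or VGF library 3 (0.0598), and 81.7% of its exonic bases lie in another gene of the same strand. Erythroid markers summed to 0.310 to 0.763 CPM in A549 libraries, and only 1 was tested.

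**Figure D5:**
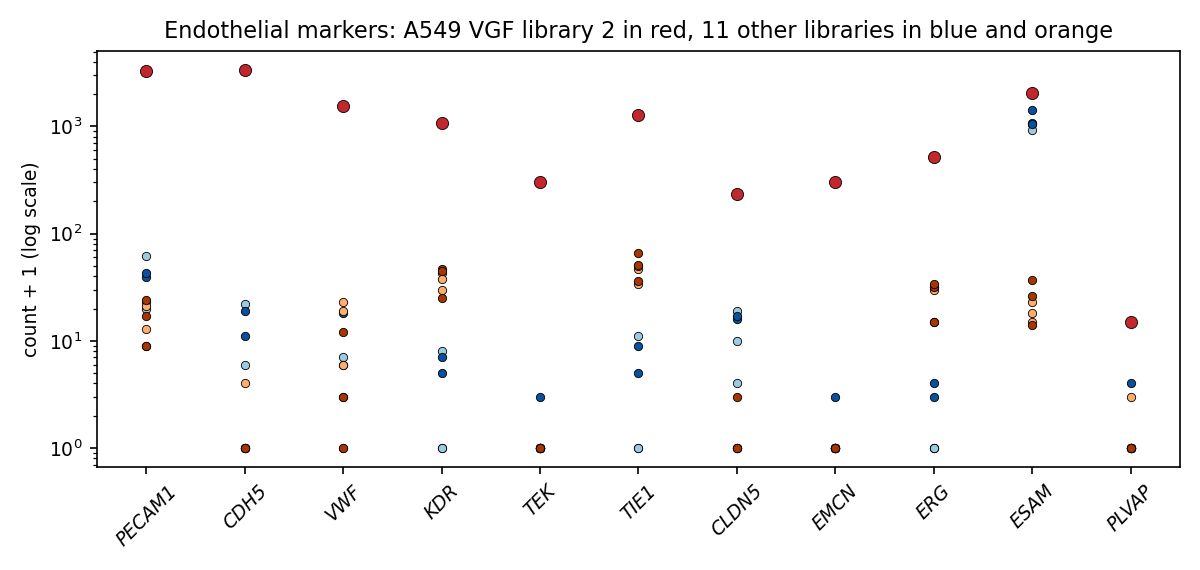
Counts plus 1 (logarithmic axis) of 11 endothelial marker genes in each of the 12 libraries, with A549 VGF library 2 in red. In that library PECAM1 and CDH5 reach 3305 and 3387 counts, while no other A549 library exceeds 61 and 21.

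In H1299, VGF overexpression raised VGF and lowered 1 gene, NRCAM, a neuronal cell adhesion molecule (ENSG00000091129, chromosome 7, 108147623 to 108456717, minus strand). NRCAM fell from 1.89 ± 0.0512 to 0.975 ± 0.181 CPM (SD, n = 3), a log2 fold change of -0.95 (SE 0.115, adjusted p = 0.0186). Counts were 87, 81 and 78 with empty vector and 46, 31 and 43 with VGF. It lies under 5 CPM in H1299 and was singled out after its values were seen. At an unadjusted p under 0.05 there were 1422 features in H1299, or 7.80%, and DESeq2 called 47 genes higher and 92 lower. NRCAM lost its call without A549 VGF library 3 (0.0516), H1299 control library 1 (0.0570), 2 (0.0680) or 3 (0.0992) or H1299 VGF library 3 (0.0513). The number of genes lower was 0 without A549 VGF library 3 or H1299 control library 2 or 3, 2 without A549 VGF library 1 or H1299 control library 1, and 3 without A549 VGF library 2 or H1299 VGF library 2.

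Gene lists moved in H1299 by small amounts, without a member called over all genes. Heat shock genes rose, with 12 of 15 positive and a median of 0.11 (camera, adjusted p = 1.65e-06; adjusted p = 0.148 with an estimated correlation), and 4 rose when adjusted over the list alone. The chaperones HSPA8 and HSP90AA1 stood at 1902 ± 138 and 2347 ± 45.2 CPM and at 3163 ± 191 and 3801 ± 214 CPM (adjusted p = 0.119 and 0.164). Nuclear oxidative phosphorylation genes rose by a median of 0.069, with 32 of 36 positive (adjusted p = 4.99e-08; adjusted p = 0.148 with an estimated correlation), led by NDUFB8 and UQCRC2 (adjusted p = 0.450 for both). Ribosomal protein genes rose by 0.055, with 50 of 53 positive (adjusted p = 2.38e-09; adjusted p = 0.270 with an estimated correlation), led by RPL24 and RPS13 (0.381 and 0.452). Cholesterol synthesis genes rose by 0.070, with 20 of 25 positive (adjusted p = 5.48e-05; adjusted p = 0.292 with an estimated correlation), among them ACAT2 and MVD (0.229 and 0.525). YAP/TEAD targets rose by 0.071, with 16 of 25 positive (adjusted p = 0.000921; adjusted p = 0.270 with an estimated correlation), led by AMOTL2 and IGFBP3 (0.142 and 0.172). When adjusted over the list alone, 1 cholesterol gene and 3 YAP targets rose and no ribosomal or oxidative phosphorylation gene did.

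Cell cycle genes in H1299 rose by a median of 0.041, with 35 of 48 positive (camera, adjusted p = 0.0158; adjusted p = 0.597 with an estimated correlation), led by CDC6 and CDC20 (adjusted p = 0.487 and 0.568). ERK output genes rose by 0.063, with 17 of 26 positive (adjusted p = 0.0354; adjusted p = 0.405 with an estimated correlation). Of these, DUSP5 stood at 74.6 ± 6.98 and 94.4 ± 2.72 CPM and ETV5 at 189 ± 11.7 and 169 ± 4.52 CPM (adjusted p = 0.148 and 0.512). When adjusted over the list alone, no cell cycle gene and 1 ERK output gene rose. The cell cycle call was lost without H1299 control library 3 (0.601) or VGF library 2 (0.492). The ERK call was lost without H1299 control library 1 (0.170) or 3 (0.0775) or VGF library 2 (0.0558) or 3 (0.166).

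ATF4 and amino acid response genes fell in H1299, with 4 of 31 positive and a median of -0.11 (camera, adjusted p = 2.54e-06; adjusted p = 0.270 with an estimated correlation), and 3 fell when adjusted over the list alone. The folate enzyme ALDH1L2 stood at 55.1 ± 4.45 and 43.3 ± 0.330 CPM, and the cystine transporter SLC7A11 at 132 ± 15.7 and 103 ± 8.34 CPM (adjusted p = 0.148 and 0.151). Mitochondrially encoded genes fell, with a median of -0.09 and 1 of 13 positive (adjusted p = 0.00352, and 0.315 without H1299 VGF library 1; adjusted p = 0.585 with an estimated correlation), led by MT-ND4L and MT-ND4 (0.512 and 0.622). NRF2 target genes fell by 0.107, with 3 of 30 positive (adjusted p = 9.04e-05; adjusted p = 0.292 with an estimated correlation), led by SLC7A11 and OSGIN1 (adjusted p = 0.368), and 2 fell when adjusted over the list alone. Collagens and matrix genes fell by 0.144, with 8 of 37 positive (adjusted p = 0.000921; adjusted p = 0.292 with an estimated correlation), led by VCAN and LAMB1 (0.372 and 0.450). TGF-beta pathway genes fell by 0.135, with 4 of 25 positive (adjusted p = 0.00352; adjusted p = 0.270 with an estimated correlation), led by TGFBI (28.8 ± 1.74 and 21.2 ± 1.29 CPM, adjusted p = 0.0704, and 0.0428 without A549 VGF library 2) and FST (0.368). Lung lineage genes fell by 0.155, with 5 of 17 positive (adjusted p = 0.00375; adjusted p = 0.270 with an estimated correlation), led by TP63 (0.148) and HNF4A (0.5002), whose counts were 4, 11 and 0 with empty vector and 0 with VGF. Epithelial genes fell by 0.251, with 9 of 29 positive (adjusted p = 0.0354; adjusted p = 0.292 with an estimated correlation), led by DSP and ELF3 (0.142 and 0.584). When adjusted over the list alone, 1 TGF-beta gene rose and 4 fell, 1 lung lineage gene and 1 epithelial gene fell, and no collagen or mitochondrial gene passed.

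One H1299 library moved with several of these falling lists, a check made after the values were seen. 44 genes above 100 CPM in every A549 library, with a median under 0.3 CPM in H1299, summed in H1299 control library 2 to 0.158% of their A549 level, against 0.0192 to 0.0272% in the other 5 H1299 libraries. The aldo-keto reductase AKR1B10 had 854 counts in control library 2 against 38 to 91, AKR1C3 151 against 0 to 15, and the aldehyde dehydrogenase ALDH3A1 272 against 13 to 33. Without that library the adjusted p was 0.324 for NRF2 targets, 0.172 for TGF-beta genes, 0.309 for epithelial genes, 0.0485 for collagens and 0.0159 for lung lineage genes. The epithelial call was also lost without H1299 VGF library 1 (0.0511) or 2 (0.136), and the lung lineage call without H1299 control library 3 (0.0929) or VGF library 1 (0.0505). The heat shock, oxidative phosphorylation, ribosomal, cholesterol, YAP, ATF4 and collagen lists kept their calls whichever of the 12 libraries was left out. The other lists did not pass in H1299, with adjusted p values of 0.0813 to 0.971.

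The lines were compared for genes that VGF changed in both. Apart from VGF, 0 genes were higher in both lines and 1, NRCAM, was lower in both, against 0.00384 expected by chance (Fisher's exact test over 18227 genes, p = 0.00384). With a single H1299 call apart from VGF, this p is only the share of those genes that were lower in A549. Both contrasts also share 1 estimate of spread per gene, so the calls are not independent and the p is no measure of support for NRCAM. In A549 NRCAM fell from 416 ± 16.7 to 342 ± 1.33 CPM (-0.28, SE 0.0511, adjusted p = 0.0309), a call lost with any A549 library left out (0.0608 to 0.0861). DESeq2 called 6 genes higher in both lines and 6 lower. Of the 143 genes called in A549 (VGF left out), 53.1% had the same sign in H1299 (exact 95% interval 44.6 to 61.5%). Among the 116 of them with a mean of at least 5 CPM in H1299 the share was 53.4% (interval 44.0 to 62.8%). It was close to the 52.3% over all genes at that level. The intervals treat genes as independent, which they are not.

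The difference between the VGF effects passed for 29 genes, 16 with a higher and 13 with a lower effect in H1299, a balance that DESeq2 turned to 122 and 196. SHISA3, KHDRBS3, RNF128 and FBN2 fell in A549 and had log2 fold changes of -0.51, -0.35, 0.18 and -0.09 in H1299, with differences of 3.37, 2.34, 1.27 and 0.69 (adjusted p = 0.0125, 0.0288, 0.0321 and 0.0181). MAGEA3 and MAGEA6 rose in A549 and stood at 137 ± 4.34 and 144 ± 3.42 CPM and at 134 ± 2.84 and 141 ± 1.40 CPM in H1299, with differences of -1.14 and -0.70 (adjusted p = 0.000534 and 0.0125). The kinase PAK3 (ENSG00000077264, chromosome X, 110944285 to 111227361, plus strand) went from 0.365 CPM to no count in A549, at least 12.6-fold lower, and from 9.16 ± 0.621 to 8.56 ± 1.28 CPM in H1299 (adjusted p of the difference 0.0111; the difference reversed with FPKM plus 1, to a PAK3 log2 fold change, interaction of line and vector, of -0.065). The adhesion receptor ADGRB3 went from 2.37 ± 0.272 to 0.126 ± 0.110 CPM in A549 and from 6.69 ± 0.337 to 7.43 ± 0.844 CPM in H1299 (difference 4.27, adjusted p = 0.0125). The zinc finger gene ZNF793 went from no count to 0.171 CPM in A549, at least 5.56-fold higher, and from 23.6 ± 1.72 to 22.7 ± 0.985 CPM in H1299 (adjusted p = 0.0208). The folds of 12.6 and 5.56 leave out the counting error of the A549 group that had counts.

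DUSP5 fell in A549 and was not called in H1299, with a difference of 0.76 (adjusted p = 0.0125). WIPF1, an actin regulator, rose in A549 from 55.5 ± 1.10 to 77.1 ± 2.46 CPM (adjusted p = 0.00236), with a difference of -0.62. CDCA7L, a MYC-interacting factor, rose in A549 from 31.5 ± 0.306 to 43.6 ± 0.441 CPM (adjusted p = 0.000631), with a difference of -0.47 (adjusted p = 0.0125 for both differences). TGFBI, not called in either line, differed by -0.73 (adjusted p = 0.0125). Of the 11 genes named by the rule for this difference, apart from VGF, 7 kept the call whichever library was left out. SHISA3 lost it without H1299 VGF library 1 (0.0518), KHDRBS3 in 9 of 12 cases (up to 0.0880), RNF128 in 9 (up to 0.107) and ZNF793 in 7 (up to 0.0694). The count of 29 was 19 without A549 control library 1, 18 without H1299 control library 2 and 19 without H1299 VGF library 1.

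With empty vector, the lines differed in 14067 of 18228 features, 7024 higher and 7043 lower in H1299, of which 3824 and 4310 exceeded 1 on the log2 scale. Interferon-stimulated genes were lower in H1299, 39 of 41 passing with a median of -3.24, as were all 30 NRF2 targets (median -3.53) and all 13 mitochondrially encoded genes (median -1.27). NF-kB and cytokine genes were lower for 24 and higher for 8 of 32 (median -3.15), TGF-beta pathway genes lower for 20 and higher for 5 of 25 (median -1.30), and epithelial genes lower for 17 and higher for 4 of 29 (median -2.52). Higher in H1299 were 40 of 53 ribosomal protein genes, with 9 lower (median 0.50), 23 of 31 ATF4 targets, with 6 lower (median 0.95), and 29 of 48 cell cycle genes, with 10 lower (median 0.44). Collagens and matrix genes were lower for 24 and higher for 10 of 37 (median -1.87). These counts are of genes called over all genes tested, and adjusted over the list alone they were the same except for collagens, with 25 lower. The lines differ in growth medium as well as in origin.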

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

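Chosen only after the results were seen were the tests on endothelial transcripts, on the number of calls per line, on the sign that A549 calls share with H1299 and on the cell cycle list, except the one that leaves out each A549 library for that list.

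The effect of VGF differed between the lines for 29 genes by an interaction test. For VGF itself the log2 fold change in H1299 minus that in A549 was -5.52. Genes with a lower effect in H1299 were ZNF793 (-5.74), MAGEA3 (-1.14), TGFBI (-0.73), MAGEA6 (-0.70), WIPF1 (-0.62) and CDCA7L (-0.47). Genes with a higher effect in H1299 were PAK3 (6.71), ADGRB3 (4.27), SHISA3 (3.37), KHDRBS3 (2.34), RNF128 (1.27), DUSP5 (0.76) and FBN2 (0.69). The fitted values of PAK3 and ZNF793 rest on a group without counts and are no bounds, and with FPKM plus 1 the PAK3 log2 fold change, interaction of line and vector, reversed to -0.065. Of 50 splits of the libraries, the real one among them, the real one gave the most genes, 29 against at most 25, a share of 0.02. The splits were drawn from combinations of relabelled lines, and a combination can keep the real labels of 1 line. A high count can then come from that line alone, so the share does not exclude chance for a difference between the lines.

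15 gene lists differed between the lines by the same test with camera. TGF-beta pathway genes had a median difference of -0.40 (adjusted p = 4.05e-05; adjusted p = 0.350 with an estimated correlation), and 1 had a higher and 6 a lower effect in H1299 when adjusted over the list alone. Cell cycle genes had -0.15 (adjusted p = 1.1e-07; adjusted p = 0.440 with an estimated correlation), heat shock genes 0.20 (0.000426; adjusted p = 0.350 with an estimated correlation), ATF4 targets -0.094 (0.000652; adjusted p = 0.440 with an estimated correlation) and mesenchymal genes -0.27 (0.00888; adjusted p = 0.440 with an estimated correlation). When adjusted over the list alone, 3 cell cycle genes, 3 ATF4 targets and 2 mesenchymal genes had a lower effect in H1299, and 6 heat shock genes had a higher and 2 a lower one. These 5 lists kept their call whichever library was left out.

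The other 10 lists lost their call without at least 1 library. Collagens and matrix genes differed by -0.24 (adjusted p = 0.0238; adjusted p = 0.565 with an estimated correlation), with 0.205 without A549 VGF library 2 and 0.142, 0.0628 and 0.216 without H1299 control library 2, VGF library 1 or VGF library 2. The unfolded protein response list differed by 0.084 (0.0172; adjusted p = 0.488 with an estimated correlation), with 0.124 without A549 control library 3 and 0.0991 without H1299 VGF library 2. Oxidative phosphorylation genes differed by 0.062 (0.00888; adjusted p = 0.440 with an estimated correlation), with 0.146 without H1299 VGF library 2. Endothelial markers differed by -6.64 (0.00888; adjusted p = 0.565 with an estimated correlation), with 0.132 without A549 VGF library 2. Receptor tyrosine kinase and EGF family genes differed by 0.16 (0.0381; adjusted p = 0.440 with an estimated correlation) and lost the call with 7 of the 12 libraries (up to 0.178).

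Cholesterol genes differed by 0.081, against the sign of their mean (adjusted p = 0.0313; adjusted p = 0.572 with an estimated correlation), and lost the call with 6 of the 12 libraries (up to 0.273). Fatty acid genes differed by 0.078 (0.0449; adjusted p = 0.440 with an estimated correlation; lost with 10 libraries, up to 0.188) and NRF2 targets by -0.11 (0.0449; adjusted p = 0.606 with an estimated correlation; lost with 6, up to 0.879 without H1299 control library 2). Angiogenesis regulators differed by -0.25 (0.0443; adjusted p = 0.572 with an estimated correlation; lost with 7, up to 0.543 without A549 VGF library 2). Leukocyte markers, of which 5 were tested, differed by 0.49 (0.0313; adjusted p = 0.350 with an estimated correlation; lost with 9, up to 0.273).

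A549 VGF library 2 held far more counts of 9 of the 11 endothelial markers than any other A549 library. An effect of VGF on endothelial genes is argued against as the source of that level, since the markers summed to at most 40.2 CPM in the other A549 VGF libraries and to 334 CPM in library 2. RNA of H1299 cells is argued against, since no H1299 library exceeded 4.27 CPM. Of the second list of 20 endothelial genes, 14 had at least 20 counts there and at least 10 times the highest other A549 library, so RNA of endothelial cells in that library is a candidate explanation. Without that library the list was still called, with a median of 0.80 (camera, adjusted p = 0.0145), but apart from ESAM its counts were low. A549 control library 3 held 61 counts of PECAM1 and 21 of CDH5. VGF libraries 1 and 3 held 38 and 42 of PECAM1 and 10 and 18 of CDH5. VWF went the other way, with 0 in that control against 17 and 5. A small rise stays open on such counts.

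More genes were called in A549, 144, than in H1299, 2, and DESeq2 called 736 and 139. Fewer counts in H1299 are argued against, since its mean library total was 107% of the A549 mean, and the endothelial transcripts as the whole cause are argued against by the 96 calls left without that library. The median SD between replicates in H1299 was 0.956 of that in A549, with the 2 H1299 groups on either side of the A549 groups, which alone does not decide on spread. The main fit used 1 estimate of spread per gene for both lines, so a larger spread in H1299 could not raise the bar for H1299 alone. That argues against a larger H1299 spread as the cause of the gap in the main fit. Each line fitted alone gave 179 calls in A549 and 4 in H1299. Those fits cannot decide on spread, since each used the estimate of its own line. The VGF step was smaller in H1299 (-5.52), and it cannot be told apart from other differences between the lines, since 2 lines cannot show a trend. The A549 calls shared a sign with H1299 in 53.1%, which leaves open whether they move alike there.

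Cell cycle genes were higher with VGF in A549. The endothelial library as the cause is argued against by the median of 0.183 without it, and a single A549 library setting the call by the highest adjusted p of 7.72e-13 over the 6 leave-outs. The growth state of the cultures at harvest could also move the whole list. It cannot be told apart from an effect of VGF, since growth state was not measured, and the adjusted p = 0.282 with an estimated correlation would arise under both. An effect of VGF on proliferation stays a hypothesis.

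For A549, for H1299 and for the lines with empty vector, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 144 genes in A549 and the highest other 0. In H1299 the real split gave 2 and the highest other 2. Between the lines the real split gave 14067 and the highest other 0.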

How the results depend on the processing

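The fit without A549 VGF library 2, the robust fit and the one with Ensembl IDs alone were chosen only after the results were seen.

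With each library left out in turn, VGF rose by 8.92 to 9.14 in A549 and by 3.42 to 3.59 in H1299 on the log2 scale. The count of genes ranged from 23 to 76 higher and from 23 to 64 lower in A549, was 1 higher and ranged from 0 to 3 lower in H1299, and was 0 higher, 0 to 1 lower and 0 to 1 opposite in both lines. Between 18 and 36 genes differed in their VGF effect, and 13610 to 14346 differed between the lines. The number of list calls was 29 to 39, against 41 with all libraries, and these totals include lists newly called.

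DESeq2 called 437 genes higher and 299 lower in A549, 47 and 92 in H1299, 6 and 6 in both lines, 4 in opposite directions and 318 for the difference in effect. Limma voom called 155 and 179 in A549, 0 lower in H1299, 0 lower in both lines and 19 for the difference. Each line fitted alone gave 3 genes higher in H1299 and 0 lower in both lines. Without a filter 2 genes were higher and 3 lower in H1299, and 1 was opposite. A log2 fold change of at least 1 left 15 higher and 21 lower in A549, 0 lower in H1299, 0 lower in both lines, 17 for the difference and 8134 between the lines, by its construction.

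FPKM plus 1 gave 0 genes lower in H1299, 0 lower in both lines and 18 for the difference. FPKM plus 0.1 gave 28 higher and 34 lower in A549, 3 and 4 in H1299, 0 lower in both lines and 16 for the difference. FPKM plus 1 with no filter gave 91 higher and 156 lower in A549, 3 higher in H1299 and 0 lower in both lines. The PAK3 log2 fold change, interaction of line and vector, reversed to -0.065 with FPKM plus 1, filtered or not. With VGF removed, 0 genes were higher in H1299. Without the library with endothelial transcripts 45 genes were lower in A549, 3 were lower in H1299, 0 were lower in both lines and 1 was opposite. Robust empirical Bayes gave 2 higher and 4 lower in H1299, 1 opposite and 45 for the difference. Ensembl IDs alone gave 2 higher and 4 lower in H1299 and 1 opposite. Of the 41 list calls, 0 were kept by camera with an estimated correlation and 2 by fry. Except where the construction of an alternative shows it, the cause was not tested.

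Replicate numbers did not pair the libraries: the correlation of control and VGF deviations with the same number was -0.066 to -0.01. With a block of replicate number, 42 genes were higher and 21 lower in A549, 0 lower in H1299 and 0 lower in both lines. The difference in effect then passed for 21 genes, 4 with a higher and 17 with a lower effect in H1299, of which 7 were among the 29.

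Among the named genes, 906 results with a library left out kept their side of the threshold, 153 lost it and 9 gained it. Under the other alternatives chosen in advance 976 kept it, 111 lost it, 42 gained it and 2 reversed. Of the list calls, 409 were kept and 83 lost with a library left out, and 121 were kept and 84 lost under the other alternatives chosen in advance.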

Other observations

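None of the values in this part was tested for an explanation, and the genes and checks were chosen only after their values were seen.

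Several genes called in A549 had no count in 1 group. TENM2 had 0.8 CPM with empty vector and none with VGF, at least 27.5-fold lower, and PKHD1 was at least 19-fold lower. ANGPTL6, GLB1L3, HOXA11 and TDRD9 were at least 6.8-fold, 6.46-fold, 3.4-fold and 3.06-fold lower. ERICH6 and ZNF649 had no count with empty vector and were at least 12.1-fold and 6.21-fold higher with VGF. The floor was 3 counts over the group. The counting error of the group with counts was left out, so these folds are no strict bounds.

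A549 VGF library 2 held 125 features seen in it alone, against 3 to 13 in the other libraries. It also held 51 counts of CDKN2A and 30 of CDKN2B. 15 genes above 100 CPM in every H1299 library, with a median under 0.3 CPM in A549, summed there to 0.692% of their H1299 level, against 0.00703 to 0.0478% in the other A549 libraries. Only 4 of the 15 were highest in that library and 6 were highest in A549 control library 1, so a few genes carried the sum. Leukocyte markers summed to 67.1 CPM in that library and to between 69.0 and 94.0 CPM in the other A549 libraries, and fibroblast markers to 45.3 CPM against at most 38.3 CPM.

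Within A549 the first principal component (36.6% of the variance) parted the vectors, with control libraries at -11.1, -9.07 and -13.8 and VGF libraries at 6.88, 16.5 and 10.5. Within H1299 it held 27.2%, with control libraries at 1.01, 14.1 and 4.45 and VGF libraries at -10.6, -9.03 and 0.0496.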
